A study of Bos taurus with 36 samples.

How the data were processed

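The deposited files hold, for each of 36 arrays, the mean perfect-match intensity of every target sequence, per the file headers, from a Cy3-labelled oligonucleotide array with 45255 targets. Of these, 40808 carry 2 probes and 4447 carry 1. The values are whole numbers, their distribution differs between arrays, and no scaling or background subtraction is visible in them, while the scanner and any earlier step are not stated. The same deposited files give the coefficient of variation between the probes of a target as a ratio, which was not used in a test. The authors also deposited a table of processed values of linear intensity, with column medians between 589.929 and 624.69 and lowest values between 5.6368 and 6.8804. This table appears to be background-corrected and normalised between arrays, though how is not stated, and each of its 36 columns correlated best with its own scanner file (r on the log2 scale between 0.933 and 0.970).

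Raw intensities were background-corrected with the normexp method of limma 3.58.1 under R 4.3.3 (offset 50), quantile-normalised between arrays and converted to log2. Samples were grouped by region (4), treatment and time into 12 groups of 3 arrays, with the animal number as replicate. A linear model of limma with a term per group and a term per cow was fitted to all targets on all 36 arrays, followed by empirical Bayes moderation. Two-sided p values were adjusted by the Benjamini-Hochberg method over the 45255 targets, and a target was called at an adjusted p under 0.05. The 17 comparisons were E. coli against PBS at 12 h and at 24 h in each region, 24 h against 12 h in each region, the mean response of rosette and teat cistern minus the response of lobuloalveolar tissue at each time, and each other region against lobuloalveolar tissue in PBS glands. PBS was given at 24 h only and served as the control at both times, so that the 12 h and 24 h responses share their controls. The 12 h gland and the 24 h gland of a cow are different glands, so time and gland cannot be separated within a cow, while the positions of these glands differ between cows. Deviations of arrays from their group means, without a term for cow, correlated at a mean r of 0.228 over 198 pairs from the same cow. For pairs from other cows the mean r was -0.113 over 396 pairs. Deviations cancel out over the 3 cows of a group, so the negative value follows from the positive one and is no separate evidence.

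Gene names came from the protein descriptions in the array files. Symbols of listed genes were assigned through the UniProt entry names and protein names in these descriptions. Of the listed symbols, 752 appear in a bovine RefSeq gene table. Of all targets 24320 received a name, giving 16129 named genes, and 17692 had no description. Names rest on similarity of sequence in most cases: 10583 descriptions are qualified as similar and 9728 as homologues. The 1968 targets described as weakly similar received no name. Cross-hybridisation between close family members was not tested. There were 30 gene lists with 793 genes, of which 600 had a target. After values were first seen, 49 assignments of targets to listed genes were added and 31 removed, on the wording of the names alone. A gene with several targets was represented by the target with the highest mean over all arrays. Lists were tested with camera of limma on named genes with a preset correlation of 0.01, adjusted over the lists and comparisons of a family, and again with a correlation estimated from the data. The list shifts passed in 127 of 240 tests of E. coli against PBS, 55 of 120 of 24 h against 12 h, 29 of 60 of response differences and 26 of 90 between PBS regions. With an estimated correlation 27, 3, 6 and 0 of these passed, respectively. The smallest adjusted p between PBS regions was then 0.217.

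The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. For E. coli against PBS the rule takes, among named genes that passed and changed in the same direction in all 3 cows, the 8 largest rises and 6 largest falls, then up to 4 members per list by p, and a fixed set of mastitis genes whether or not they pass. For 24 h against 12 h and for response differences it takes the 6 leading genes each way and the fixed set, and for PBS regions the 6 leading genes each way and up to 3 members per list. Of the genes so chosen, the text names a part. CXCL5, NFKBIA, SAA3 and LCN2 have no target assigned under their symbols and are not analysed here, and S100A12 is given under an older protein name only. Targets without a name are counted and not named. Single results of 3 genes are not reported here, while the fits and list tests include them.

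Alternatives changed 1 choice at a time: no term for cow, the arrays of the compared regions alone, the gland as a random block, median scaling, no background correction, the authors' processed values, targets brighter than the median target only, the mean of all targets of a gene, an estimated correlation, and leaving out each cow. The arrays of cow 2661 from the rosette at 24 h and from the gland cistern at 12 h were also left out, and the mean of the neutrophil list was added as a covariate, all of which were chosen after seeing the data. The fit was tested on simulated data made like 3 of the comparisons. Of 100 targets changed by log2 1 it recovered 54 for the teat cistern at 12 h, 41 for the response difference at 24 h and 60 for the PBS rosette, with 91, 86 and 89 recovered at log2 2. False calls numbered 7, 8 and 14. A list of 30 genes shifted by log2 0.5 was found in each of the 3 simulations, and an unshifted list had p of 0.174, 0.858 and 0.530 by camera. The simulated noise was drawn independently for every target and array, without correlation between genes or an effect of gland. The simulations therefore cannot show how the tests behave where genes or arrays of a gland vary together.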

Results

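Total RNA from the udders of 3 lactating Holstein cows was labelled with Cy3 and hybridised to 36 oligonucleotide arrays, 1 array per tissue sample, each measuring 45255 target sequences. In every cow a mammary gland of the udder, each with its own teat, had received phosphate-buffered saline (PBS). Another gland had received 400 colony forming units of Escherichia coli in 4 mL, as long before collection as the saline, 24 h, and the last of the 3 glands the same bacterial dose 12 h before collection. Each of these 3 glands was sampled in 4 regions: Fürstenberg's rosette, a ring of mucosal folds at the inner end of the teat canal; the teat cistern, the milk space of the teat; the gland cistern above it; and the lobuloalveolar tissue, where milk is made. This gives 12 groups of 3 arrays. The median raw intensity of an array lay between 697 and 1372, and its 5th percentile between 161 and 293. The number of arrays limits the precision. Changes are log2 values, followed after ± by the standard error of the limma fit for genes and the standard error over the 3 cows for the means of gene lists. Genes said to rise, fall, or be higher or lower passed at an adjusted p under 0.05. Each group has n = 3, every named gene that passed the test changed in the same direction in 3 of 3 cows in the fitted comparison, and genes are written by symbol or by the protein name that the array files give. A gene with several targets is represented by its brightest, and for CXCR2 (2 targets), HP and PTGS2 (3 each) not every target passed where the gene did, except HP in the PBS teat cistern. The same holds for KRT15 at 12 h, MT1A, CSN1S1, CCL5, L-serine dehydratase, ADGRE1, SQLE, ACACA, CUL7 and THY1.

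The regions were compared in PBS glands, which belong to cows whose other sampled glands had received E. coli. In the rosette, genes of a stratified, cornifying epithelium stood far above their lobuloalveolar level. Corneodesmosin, an adhesion protein of the horny layer, was higher by log2 8.21 ± 0.74, desmocollin 1 by 7.63 ± 0.68 and desmoglein 1 (DSG1) by 6.23 ± 0.62. The envelope protein SPRR1A was higher by 7.35 ± 0.57 and the basal keratin KRT14 by 6.20 ± 0.70 (adjusted p of all these genes at most 6.07e-07). Of 24 squamous markers, 22 were higher and 1 lower, with the same counts adjusted over the list alone (mean log2 3.61 ± 0.12, adjusted p = 5.01e-15, and adjusted p = 0.217 with an estimated correlation). Cell division genes were also higher, 20 of 26 singly and as many adjusted over the list alone, among them RRM2 at 5.29 ± 0.52 and NDC80 at 3.77 ± 0.47 (mean log2 1.58 ± 0.11, adjusted p = 9.28e-08, and adjusted p = 0.678 with an estimated correlation). The calgranulins S100A8 and S100A9, carried by neutrophils and by keratinocytes, were higher by 6.58 ± 0.42 and 5.91 ± 0.44. For the chemokine receptor CXCR2 the difference was 5.03 ± 0.38. These transcripts were already abundant in the rosette of PBS glands, CXCR2 at a mean raw intensity of 3757. Lower than in lobuloalveolar tissue were butyrophilin (BTN1A1), a milk fat globule protein, at -6.55 ± 1.10, lipoprotein lipase (LPL) at -4.71 ± 0.67, the mucin MUC1 at -4.14 ± 0.67 and adiponutrin at -6.20 ± 1.07. The milk protein list fell short of its lobuloalveolar level with 7 of 15 members lower, also 7 adjusted over the list alone (mean log2 -1.84 ± 0.40, adjusted p = 6.37e-04, and adjusted p = 0.678 with an estimated correlation). The milk lipid and lactose list had 19 of 31 lower and 3 higher, or 19 and 4 adjusted over the list alone (mean log2 -1.0 ± 0.06, adjusted p = 6.37e-04, and adjusted p = 0.678 with an estimated correlation). In all, 13629 targets differed between rosette and lobuloalveolar tissue, 6640 of them higher in the rosette. The count was 7521 without cow 2829 and 7204 without cow 2851. Under median scaling in place of quantile normalization 33.2% of the differing targets were higher in place of 48.7%.

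The PBS teat cistern carried a contractile and connective tissue profile. Relaxin receptor 2 was higher than in lobuloalveolar tissue by log2 7.19 ± 0.46, a myophosphorylase, the glycogen-degrading enzyme of muscle, by 6.94 ± 0.77 and alpha 2 actinin by 6.25 ± 0.60. Among cytoskeletal genes gamma-filamin was higher by 5.83 ± 0.67, smoothelin (SMTN) by 3.63 ± 0.45 and desmin (DES) by 2.81 ± 0.37 (adjusted p of all these genes at most 5.62e-06). Of 16 smooth muscle genes 12 were higher, 14 adjusted over the list alone (mean log2 1.93 ± 0.06, adjusted p = 9.28e-08, and adjusted p = 0.678 with an estimated correlation). Of 20 fibroblast and collagen genes 19 were higher, including tenascin C (TNC) at 4.09 ± 0.51, and 20 adjusted over the list alone (mean log2 1.44 ± 0.05, adjusted p = 2.36e-07, and adjusted p = 0.678 with an estimated correlation). The sterol synthesis genes stood lower, 16 of 18 against 1 higher and the same adjusted over the list alone (mean log2 -1.48 ± 0.11, adjusted p = 1.00e-05, and adjusted p = 0.678 with an estimated correlation), with DHCR7 at -2.75 ± 0.53 and INSIG1 at -2.90 ± 0.48. Fatty acid-binding protein FABP4, of fat and alveolar cells, was lower at -5.04 ± 0.82, and cysteine-rich secretory protein-3 at -5.67 ± 1.21. The acute phase protein haptoglobin (HP) was higher at 3.03 ± 0.64, while the receptors CD14 and TLR2, which bind bacterial products, were lower at -1.41 ± 0.44 and -1.31 ± 0.38. CD14 and TLR2 lost their calls without cow 2661 and without cow 2829, and HP without cow 2829. In the teat cistern 14124 targets differed from lobuloalveolar tissue, 7302 of them higher, with 7770 without cow 2829 and 8263 without cow 2851. Under median scaling the larger direction turned, with 41.7% higher in place of 51.7%.

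In the PBS gland cistern the 15S-lipoxygenase type 2 was higher than in lobuloalveolar tissue by log2 3.38 ± 0.72, claudin 4 (CLDN4), a tight junction protein, by 2.30 ± 0.54 and the fibroblast marker THY1 by 1.38 ± 0.27. The transcription factor REL was lower at -2.09 ± 0.46 (adjusted p of these genes between 0.0272 and 0.0413). The fibroblast and collagen list was higher as a whole, with 1 of 20 members higher and 7 adjusted over the list alone (mean log2 0.89 ± 0.30, adjusted p = 8.42e-07, and adjusted p = 0.678 with an estimated correlation). Here 563 targets differed, 234 higher and 329 lower, and 9968 at an unadjusted p under 0.05. This count rests on the settings, given with the number at an unadjusted p under 0.05 from limma wherever it was 0, here and later: it was 0 (6146 unadjusted) without cow 2661, 0 (4934 unadjusted) without cow 2829, 1565 without cow 2851, 0 (7942 unadjusted) with the arrays of these regions alone and 18 with the authors' processed values. Among targets above the median target only, the larger direction turned, with 409 of 713 higher.

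**Figure D1:**
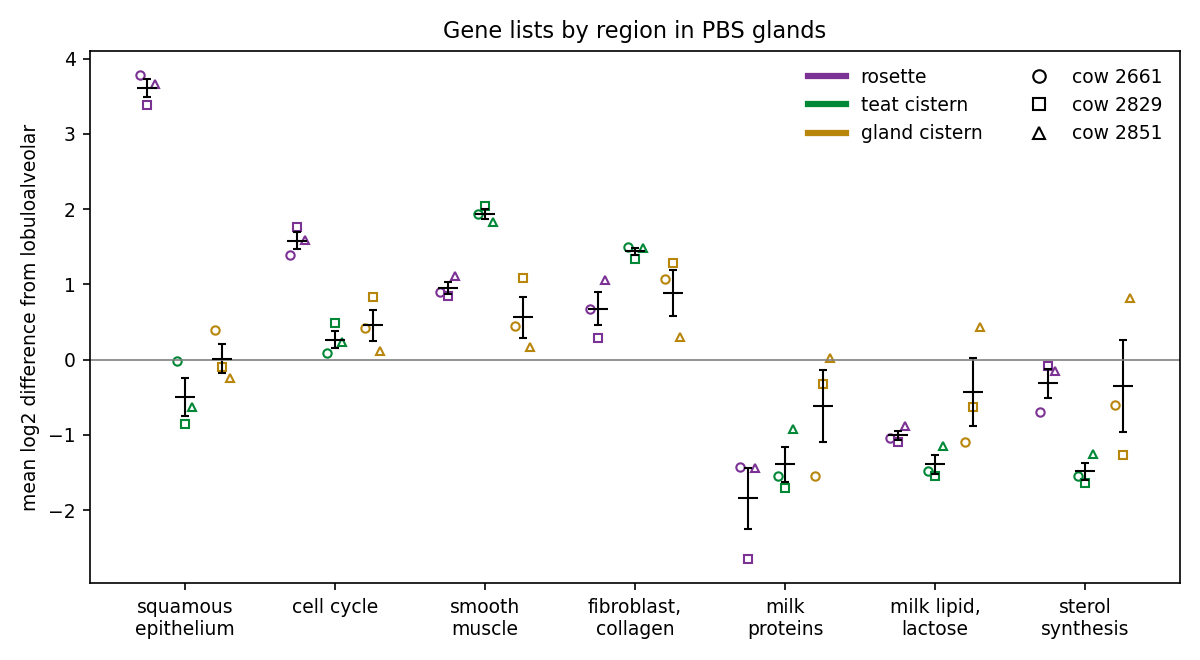
Mean log2 difference of 7 gene lists between each of 3 regions and lobuloalveolar tissue in PBS glands; open symbols are the 3 cows and black bars the mean with its standard error over cows. The squamous epithelium list stood highest in the rosette at 3.61, and the smooth muscle list in the teat cistern at 1.93.

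The comparison of E. coli with PBS glands within each region addresses which tissue responds, and how early, in a series whose title asks about a sentinel function of teat tissue. In the rosette at 12 h the response was led by chemoattractants for leukocytes. CCL20 rose by log2 6.32 ± 0.97, CXCL8 by 5.49 ± 0.68, CXCL1 by 5.28 ± 0.62, CXCL3 by 4.86 ± 0.65 and CXCL6 by 4.64 ± 0.72 (adjusted p between 7.70e-05 and 0.00244). The cytokines IL1B and IL6 rose by 4.71 ± 0.48 (adjusted p = 1.68e-05) and 4.16 ± 0.84 (adjusted p = 0.0333), the inducible nitric oxide synthase NOS2 by 5.25 ± 0.70 and the interstitial collagenase MMP1 by 3.81 ± 0.45. The epithelial defensins TAP and LAP, the tracheal and lingual antimicrobial peptides, rose by 3.64 ± 0.76 and 2.92 ± 0.49. L-serine dehydratase rose by 4.66 ± 0.64 at the brightest of its 2 targets, the other having the opposite sign. Keratin KRT19, beta-lactoglobulin (PAEP) and alpha-S1 casein (CSN1S1) fell, at -2.09 ± 0.39, -2.89 ± 0.60 and -3.0 ± 0.62 (adjusted p between 0.0150 and 0.0372), and 16 of the 17 CSN1S1 targets had this sign. TNF (3.56 ± 0.79, adjusted p = 0.0580), HP (2.71 ± 0.64, adjusted p = 0.0915) and CXCR2 (0.75 ± 0.38, adjusted p = 0.999) did not pass.

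By list, 7 of 22 chemokines rose in the rosette at 12 h, and adjusted over the list alone 12 rose and 1 fell (mean log2 1.94 ± 0.24, adjusted p = 2.17e-18, and adjusted p = 0.00265 with an estimated correlation). Inflammatory cytokines rose with 3 of 23 members past the test and 11 adjusted over the list alone (mean log2 1.25 ± 0.10, adjusted p = 3.84e-16, and adjusted p = 0.00243 with an estimated correlation). This list, here and later, also holds IL10 and the decoy receptor IL1R2, so it does not measure pro-inflammatory genes alone. Of 23 targets and feedback regulators of NF-kB, the transcription factor of inflammation, 1 passed over all targets and 17 adjusted over the list alone (mean log2 1.36 ± 0.14, adjusted p = 4.10e-24, and adjusted p = 0.00310 with an estimated correlation). The neutrophil markers shifted up, with 2 of 15 higher and 3 adjusted over the list alone (mean log2 0.85 ± 0.27, adjusted p = 1.08e-06, and adjusted p = 0.0453 with an estimated correlation). Milk proteins shifted down, 2 of 15 singly and 6 adjusted over the list alone (mean log2 -1.24 ± 0.57, adjusted p = 4.16e-09, and adjusted p = 0.0812 with an estimated correlation). Altogether 84 targets changed in the rosette at 12 h, 69 up and 15 down. CXCL1, IL1B, MMP1 and L-serine dehydratase also passed with any 1 cow left out, and each other named gene lost its call without at least 1 cow. The larger direction turned without cow 2829, with 26 of 88 targets higher and 34 shared with the main fit. Leaving out cow 2661 left 62 targets, all higher and 38 of them shared. Leaving out cow 2851 left 6 targets, and the rosette arrays fitted alone gave 0 (2832 unadjusted).

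The teat cistern at 12 h responded with chemokines, cytokines and neutrophil genes. CCL20 rose by log2 7.79 ± 0.97, CXCL8 by 7.28 ± 0.68, CXCL6 by 6.60 ± 0.72, CXCL3 by 6.18 ± 0.65, IL1B by 6.07 ± 0.48, IL6 by 5.87 ± 0.84 and TNF by 4.67 ± 0.79 (adjusted p at most 4.14e-04). Products of neutrophils rose too: S100A8 by 6.78 ± 0.42, S100A9 by 5.82 ± 0.44 and CXCR2 by 5.78 ± 0.38. Haptocorrin, a vitamin B12 carrier of neutrophil granules, rose by 6.94 ± 0.65. The transglutaminase TGM3 rose by 7.04 ± 0.46. Also higher were the receptor antagonist IL1RN at 5.82 ± 0.51, the decoy receptor IL1R2 at 4.49 ± 0.38 and IL10 at 3.56 ± 0.48. The sensors CD14, TLR2 and TLR4 rose by 2.66 ± 0.44, 2.16 ± 0.38 and 1.08 ± 0.20 (adjusted p at most 0.00119). Falls were seen for keratin KRT15 at -3.22 ± 0.55, claudin 8 (CLDN8) at -2.88 ± 0.55, cingulin (CGN) at -1.42 ± 0.29 and the mammary transcription factor ELF5 at -1.79 ± 0.42, as did the neurogenic locus notch homolog protein 3 at -2.94 ± 0.65. Leaving out 1 cow ended the calls of CGN, CLDN8 and ELF5 (cow 2851), of TLR2, TLR4 and CGN (cow 2829) and of the notch homolog (cow 2661). Lactoferrin (LTF) at -0.03 ± 0.15 (adjusted p = 0.944) and SOD2 at -0.18 ± 0.47 (adjusted p = 0.871) did not pass.

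Among the teat cistern lists at 12 h, 10 of 15 neutrophil markers rose, 11 adjusted over the list alone (mean log2 2.82 ± 0.12, adjusted p = 1.15e-13, and adjusted p = 0.00265 with an estimated correlation). Antimicrobial and acute phase genes rose in 15 of 30 cases, 17 adjusted over the list alone (mean log2 1.94 ± 0.17, adjusted p = 1.65e-14, and adjusted p = 0.00243 with an estimated correlation). For inflammatory cytokines the counts were 15 of 23, and 17 adjusted over the list alone (mean log2 2.21 ± 0.18, adjusted p = 2.32e-13, and adjusted p = 0.00265 with an estimated correlation). Chemokines rose in 14 of 22 cases both ways of adjusting, that is also 14 adjusted over the list alone (mean log2 2.69 ± 0.23, adjusted p = 1.06e-12, and adjusted p = 0.0126 with an estimated correlation). Monocyte and macrophage markers shifted up with 8 of 18 members, also 8 adjusted over the list alone (mean log2 1.26 ± 0.11, adjusted p = 6.84e-06, and adjusted p = 0.125 with an estimated correlation). Luminal epithelial markers shifted down with 4 of 21, or 8 adjusted over the list alone (mean log2 -0.67 ± 0.35, adjusted p = 8.20e-04, and adjusted p = 0.258 with an estimated correlation). The luminal list had an adjusted p of 0.294 without cow 2851. The teat cistern had 4970 changed targets at 12 h, 2585 up and 2385 down. With 1 cow fewer the count was 1962, 1897 and 1783 without cows 2661, 2829 and 2851.

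The gland cistern at 12 h also responded with chemokines, cytokines and neutrophil genes. CCL20 rose by log2 6.84 ± 0.97, CXCL8 by 6.73 ± 0.68, CXCL3 by 6.29 ± 0.65, IL6 by 5.79 ± 0.84, IL1B by 5.18 ± 0.48 and TNF by 4.13 ± 0.79 (adjusted p at most 0.00131). The neutrophil genes S100A8, CXCR2 and haptocorrin rose by 6.26 ± 0.42, 5.82 ± 0.38 and 6.45 ± 0.65. HP rose by 3.51 ± 0.64 at the brightest of its 3 targets, the others having the opposite sign. The metal-binding metallothioneins MT2A and MT1A rose by 3.90 ± 0.68 and 3.51 ± 0.60. Falls were seen for KRT15 at -3.45 ± 0.55, the GABA receptor pi subunit at -3.42 ± 0.71, SLIT and NTRK-like protein 6 at -3.76 ± 0.82 and the flagellin receptor TLR5 at -1.38 ± 0.25. Of 30 antimicrobial and acute phase genes 15 rose, 16 adjusted over the list alone (mean log2 1.84 ± 0.22, adjusted p = 2.02e-13, and adjusted p = 0.00243 with an estimated correlation). Of 15 neutrophil markers 8 rose, also 8 adjusted over the list alone (mean log2 2.37 ± 0.18, adjusted p = 1.64e-09, and adjusted p = 0.0121 with an estimated correlation). Matrix remodelling genes shifted up, 11 of 22 singly, while adjusted over the list alone 11 rose and 1 fell (mean log2 1.41 ± 0.39, adjusted p = 3.23e-07, and adjusted p = 0.0664 with an estimated correlation). Tight junction and barrier genes shifted down, with 4 of 16 lower and 1 higher, the same adjusted over the list alone (mean log2 -0.48 ± 0.11, adjusted p = 0.0210, and adjusted p = 0.289 with an estimated correlation). The barrier list had an adjusted p of 0.0521 without cow 2661 and 0.0715 under median scaling. In total 5546 targets changed, 2762 up and 2784 down. Without cow 2829 the calls of HP, KRT15, MT1A, MT2A, TLR5, TNF, the GABA receptor subunit and SLIT and NTRK-like protein 6 ended, the latter pair also without cow 2661. The number was 417 without cow 2829, 3513 without cow 2851 and 227, 198 of them up, with the gland cistern arrays fitted alone. Under median scaling 57.6% of the changed targets were up in place of 49.8%.

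Lobuloalveolar tissue at 12 h showed a small response, led by the transglutaminase TGM3, neutrophil genes and a chemokine. TGM3 rose by log2 3.80 ± 0.46, haptocorrin by 3.70 ± 0.65, CXCL3 by 3.65 ± 0.65, CXCR2 by 2.89 ± 0.38 and S100A8 by 2.53 ± 0.42. Calcium-binding protein in amniotic fluid 1, an older name of the calgranulin S100A12, rose by 2.36 ± 0.37 (adjusted p of these genes between 4.47e-04 and 0.0398). CXCL8 at 3.59 ± 0.68 (adjusted p = 0.0697), IL1B at 2.06 ± 0.48 (adjusted p = 0.221) and CCL20 at 1.67 ± 0.97 (adjusted p = 0.949) did not pass. The neutrophil list rose, 2 of 15 singly and 4 adjusted over the list alone (mean log2 0.89 ± 0.19, adjusted p = 8.66e-09, and adjusted p = 0.0150 with an estimated correlation). So did the antimicrobial and acute phase list, 1 of 30 and 7 adjusted over the list alone (mean log2 0.73 ± 0.08, adjusted p = 1.46e-10, and adjusted p = 0.00400 with an estimated correlation). Only 8 targets passed in this fit, all upward, with 2684 at an unadjusted p under 0.05, and 0 (1704 unadjusted) passed without cow 2851. Without cow 2661 the test passed 11 targets, of which 0 were among these, and without cow 2829 it passed 9, of which 3 were. Each of the 6 named genes lost its call without cow 2661 and without cow 2851. All 8 also rose in the teat cistern and in the gland cistern at 12 h, where 0.457 and 0.488 shared targets would arise from independent lists. All 69 targets that rose in the rosette rose in both cisterns too, against 3.94 and 4.21 for independent lists. The cisterns shared 1563 rises against 158. The regions compared here come from the same glands of the same cows, so their lists are not independent. The numbers for independent lists are therefore no test of a shared response.

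**Figure D2:**
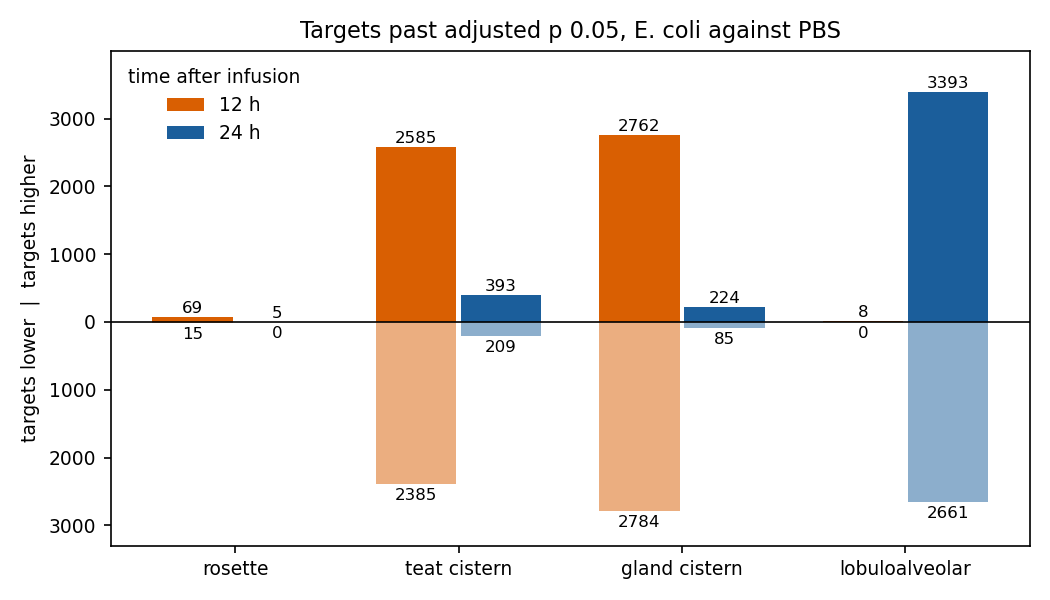
Number of targets past an adjusted p of 0.05 in E. coli against PBS glands, by region and time; bars above 0 are higher and bars below 0 lower in E. coli glands. The counts were highest at 12 h in both cisterns and at 24 h in lobuloalveolar tissue, where 3393 targets were higher.

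In the rosette at 24 h, L-serine dehydratase was higher than in PBS glands by log2 3.70 ± 0.64 (adjusted p = 0.0417), LAP by 3.30 ± 0.49 and ficolin, a lectin that starts complement, by 3.10 ± 0.48 (both adjusted p = 0.0108), and CCL5, a T cell and monocyte attractant, by 2.90 ± 0.46 (adjusted p = 0.0143). CXCL8 stood at 2.98 ± 0.68 (adjusted p = 0.258), IL1B at 1.11 ± 0.48 (adjusted p = 1.0) and S100A8 at -0.36 ± 0.42 (adjusted p = 1.0), and these did not pass. Chemokines shifted up as a list, 1 of 22 singly and 9 adjusted over the list alone (mean log2 1.31 ± 0.38, adjusted p = 4.15e-15, and adjusted p = 0.00527 with an estimated correlation). Antimicrobial and acute phase genes did so as well, 1 of 30 singly and 6 adjusted over the list alone (mean log2 0.68 ± 0.09, adjusted p = 8.23e-08, and adjusted p = 0.0150 with an estimated correlation). The cell cycle list shifted down with no member past the test either way, over all targets or adjusted over the list alone (mean log2 -0.49 ± 0.18, adjusted p = 2.22e-09, and adjusted p = 0.0976 with an estimated correlation). The squamous list also shifted down, in 2 of 3 cows, with no member past either test (mean log2 -0.52 ± 0.52, adjusted p = 2.48e-05, and adjusted p = 0.239 with an estimated correlation). Without cow 2661 the adjusted p of the squamous list was 0.714. Here 5 targets passed, the fifth without a protein name and all of them higher, and 1772 passed an unadjusted p under 0.05. The count was 0 (1036 unadjusted), 0 (2641 unadjusted) and 4 (1 of them shared) without cows 2661, 2829 and 2851, and 0 (2376 unadjusted) with the rosette arrays alone. Each named gene lost its call without cow 2661 and without cow 2829. The count was also 0 (1270 unadjusted) without the E. coli 24 h rosette array of cow 2661, left out after the results were seen.

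The teat cistern at 24 h had high levels of neutrophil and antimicrobial transcripts. TGM3 was higher than in PBS glands by log2 5.85 ± 0.46, S100A8 by 5.01 ± 0.42, S100A9 by 4.06 ± 0.44, haptocorrin by 4.93 ± 0.65 and CXCR2 by 4.06 ± 0.38. The defensins TAP and LAP were higher by 4.35 ± 0.76 and 4.34 ± 0.49 (adjusted p of these genes at most 0.00299). Pantetheinase (VNN1), an enzyme of coenzyme A turnover, was higher by 4.22 ± 0.72, ADGRE1, a receptor of the EGF-TM7 family, by 4.27 ± 0.81 and CXCL8 by 3.64 ± 0.68. A cytochrome P450 of family 2A was lower at -4.09 ± 0.95 (adjusted p of these genes between 0.00262 and 0.0289). L-serine dehydratase rose by 4.91 ± 0.64 at the brightest of its 2 targets and had the opposite sign at the other. TGM3, S100A8, S100A9, CXCR2 and LAP also passed with any 1 cow left out, unlike the other named genes. IL1B at 1.62 ± 0.48 (adjusted p = 0.0948), CCL20 at 2.90 ± 0.97 (adjusted p = 0.146) and IL6 at 1.97 ± 0.84 (adjusted p = 0.290) did not pass. Neutrophil markers were higher in 7 of 15 cases, 9 adjusted over the list alone (mean log2 1.97 ± 0.12, adjusted p = 1.02e-13, and adjusted p = 0.00265 with an estimated correlation). Monocyte and macrophage markers, including CD68 at 1.24 ± 0.20, were higher in 7 of 18, or 10 adjusted over the list alone (mean log2 1.13 ± 0.06, adjusted p = 1.08e-09, and adjusted p = 0.0377 with an estimated correlation). Antigen presentation genes shifted up, 1 of 22 singly and 6 adjusted over the list alone (mean log2 0.48 ± 0.14, adjusted p = 1.03e-04, and adjusted p = 0.359 with an estimated correlation). Here 602 targets changed, 393 up and 209 down, and without cows 2661, 2829 and 2851 the count was 69, 34 and 150.

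In the gland cistern at 24 h, TGM3 rose by log2 6.57 ± 0.46, CXCR2 by 5.60 ± 0.38, haptocorrin by 4.70 ± 0.65, S100A8 by 4.2 ± 0.42, the myeloid receptor TREM1 by 4.17 ± 0.55 and chitinase 3-like protein 2 by 4.12 ± 0.62 (adjusted p at most 7.33e-04). HP rose by 3.29 ± 0.64, the haemoglobin scavenger receptor CD163 by 1.94 ± 0.35 and the protease inhibitor TIMP1 by 2.22 ± 0.33. Falls were seen for cytochrome P450 2B11 at -3.27 ± 0.77 and flavin-containing monooxygenase 3 at -3.33 ± 0.66, as did CR2, a complement receptor of B cells, at -1.80 ± 0.40 (adjusted p at most 0.0427). The antimicrobial and acute phase list rose in 8 of 30 members, 15 adjusted over the list alone (mean log2 1.31 ± 0.12, adjusted p = 4.15e-15, and adjusted p = 0.00243 with an estimated correlation). The neutrophil list rose in 5 of 15, 8 adjusted over the list alone (mean log2 1.83 ± 0.11, adjusted p = 3.18e-13, and adjusted p = 0.00265 with an estimated correlation). TGM3, CXCR2 and S100A8 also passed with any 1 cow left out, unlike the other named genes. In this region 309 targets changed at 24 h, 224 up and 85 down. The count fell to 53 without cow 2829, 71 without cow 2851 and 11 with the gland cistern arrays fitted alone.

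Lobuloalveolar tissue had its large response at 24 h. TGM3 rose by log2 7.35 ± 0.46, CXCR2 by 7.10 ± 0.38, haptocorrin by 6.57 ± 0.65, chitinase 3-like protein 2 by 6.38 ± 0.62 and IL1R2 by 6.17 ± 0.38. Neutrophil beta-defensin 4 rose by 6.08 ± 0.41, CXCL8 by 5.94 ± 0.68, TREM1 by 5.88 ± 0.55 and HP by 5.85 ± 0.64 (adjusted p of all these genes at most 1.35e-06). IL10 rose by 3.58 ± 0.48, IL1B by 3.51 ± 0.48, IL6 by 2.63 ± 0.84 and PTGS2, the inducible enzyme of prostaglandin synthesis, by 4.2 ± 0.70 (adjusted p at most 0.0382). TNF at 2.26 ± 0.79 (adjusted p = 0.0575) and CCL20 at 2.59 ± 0.97 (adjusted p = 0.0796) did not pass. Lower were fatty acid synthase (FASN) at -4.38 ± 0.84, LPL at -3.79 ± 0.67, acetyl-CoA carboxylase (ACACA) at -1.58 ± 0.45 and the sterol enzyme SQLE at -1.17 ± 0.30 (adjusted p at most 0.0185). The complement receptor CR2 fell by 2.91 ± 0.40 and the collagen-binding lumican (LUM) fell by 1.94 ± 0.39 (adjusted p at most 0.00124). CSN2 at -0.03 ± 0.38 (adjusted p = 0.978) and LALBA at -0.12 ± 1.04 (adjusted p = 0.965) did not pass, with mean raw intensities of 51775 and 56074.7 in the E. coli glands, near the top of the scale.

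Antimicrobial and acute phase genes rose in 18 of 30 cases in lobuloalveolar tissue at 24 h, 20 adjusted over the list alone (mean log2 2.08 ± 0.11, adjusted p = 1.02e-13, and adjusted p = 0.00243 with an estimated correlation). Neutrophil markers rose in 9 of 15, and adjusted over the list alone 10 rose and 1 fell (mean log2 2.37 ± 0.22, adjusted p = 4.24e-09, and adjusted p = 0.0138 with an estimated correlation). Interferon-stimulated genes shifted up with 10 of 21 singly and 13 adjusted over the list alone (mean log2 1.02 ± 0.19, adjusted p = 4.27e-06, and adjusted p = 0.234 with an estimated correlation). The sterol synthesis list shifted down with 4 of 18, 7 adjusted over the list alone (mean log2 -0.69 ± 0.16, adjusted p = 1.63e-04, and adjusted p = 0.423 with an estimated correlation). The fibroblast and collagen list did so with 4 of 20, 8 adjusted over the list alone (mean log2 -0.74 ± 0.22, adjusted p = 2.48e-05, and adjusted p = 0.458 with an estimated correlation). Leaving out 1 cow ended the calls of FASN and LUM (cow 2829), IL6 and ACACA (cow 2829 or 2851) and SQLE (cow 2661 or 2851), and the other named genes passed with any 1 cow left out. A total of 6054 targets changed, 3393 up and 2661 down. Without cow 2829 there were 1984, and without cow 2851 there were 2162. Of the 393 rises in the teat cistern at 24 h, 309 were also rises in lobuloalveolar tissue, against 29.5 for independent lists. Both regions come from the same glands, so these lists are not independent either.

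**Figure D3:**
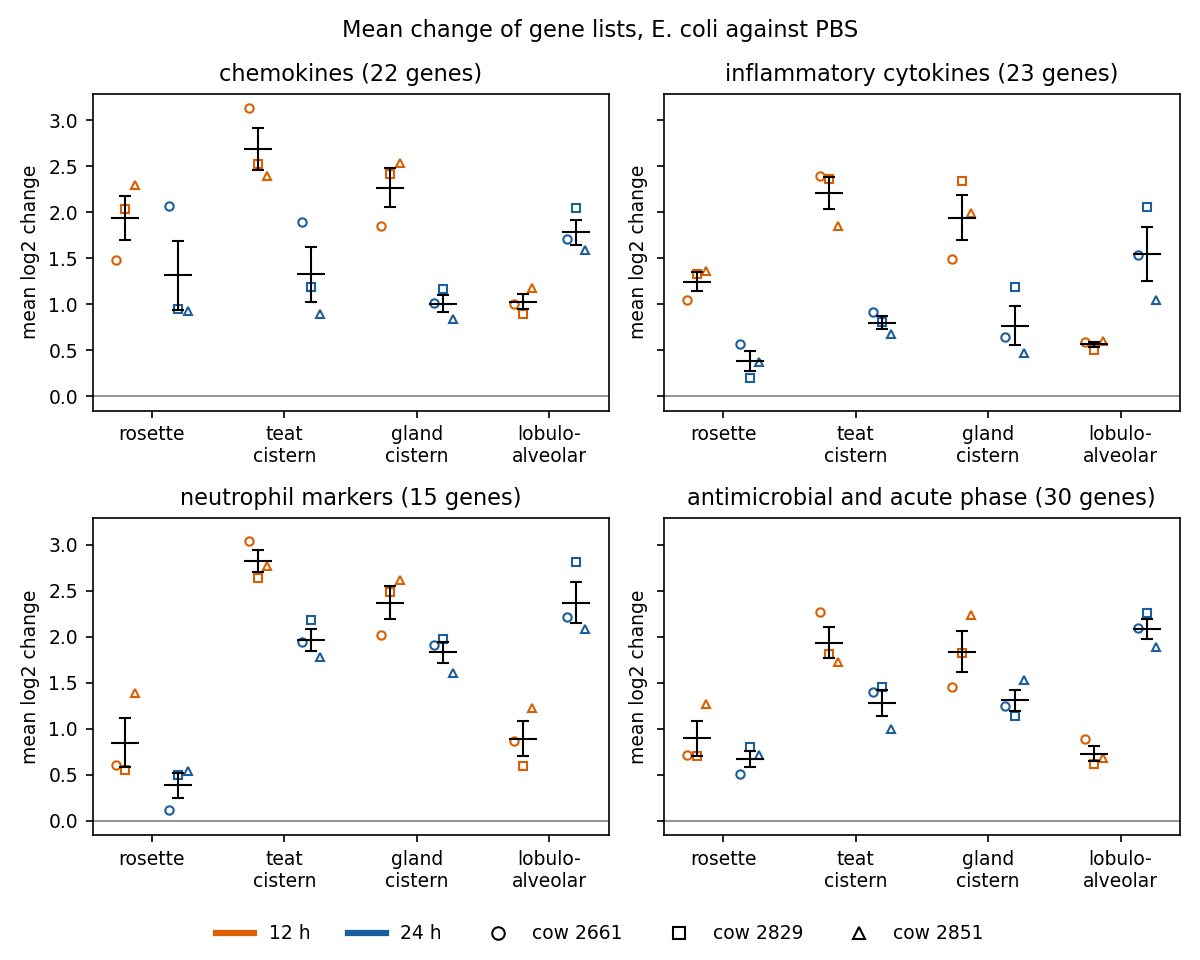
Mean log2 change of 4 gene lists in E. coli against PBS glands by region at 12 h and 24 h; open symbols are the 3 cows and black bars the mean with its standard error over cows. In the teat cistern the inflammatory cytokine list stood at 2.21 at 12 h and 0.80 at 24 h, in lobuloalveolar tissue at 0.56 and 1.55.

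The difference between E. coli glands at 24 h and at 12 h was tested within each region. Cytokine and chemokine transcripts were lower at the later time in the teat cistern: CCL20 at log2 -4.89 ± 0.97, CCL4 at -4.65 ± 0.55, IL1B at -4.45 ± 0.48, IL6 at -3.90 ± 0.84 and CXCL8 at -3.64 ± 0.68. Also lower were the early activation molecule CD69 at -4.27 ± 0.65, PTGS2 at -4.11 ± 0.70 and pyrin, an inflammasome protein, at -4.09 ± 0.58 (adjusted p of these genes between 4.96e-05 and 0.0406). Higher at 24 h were the nuclear receptor ROR-gamma at 2.15 ± 0.40 and the ubiquitin ligase subunit CUL7 at 1.17 ± 0.22. Inflammatory cytokines were lower in 6 of 23 cases, 16 adjusted over the list alone (mean log2 -1.41 ± 0.12, adjusted p = 2.37e-16, and adjusted p = 0.00330 with an estimated correlation). Neutrophil markers were lower beside them, 1 of 15 singly (CXCR2 at -1.72 ± 0.38) and 4 adjusted over the list alone (mean log2 -0.85 ± 0.20, adjusted p = 1.61e-06, and adjusted p = 0.0579 with an estimated correlation). Luminal epithelial markers were higher, none singly and 5 adjusted over the list alone (mean log2 0.67 ± 0.26, adjusted p = 5.61e-07, and adjusted p = 0.122 with an estimated correlation). In the teat cistern 133 targets differed between the times, 85 of them lower at 24 h. Each named gene lost its call without cow 2829. The count was 349, 2 and 6 without cows 2661, 2829 and 2851. With neutrophil transcripts as a covariate, an alternative chosen after seeing the data, it was 0 (4187 unadjusted), and the cytokine list stood at -0.93 (adjusted p = 9.53e-07). Epithelial markers were higher at 24 h in that fit: squamous by 0.77 (adjusted p = 0.00633 by camera) and luminal by 0.64 (adjusted p = 9.71e-04). Smooth muscle, fibroblast and collagen, and endothelium lists did not pass in it. A difference in tissue make-up between these glands was not tested. Among targets above the median target only, the larger direction turned, with 55.9% of those that differed higher at 24 h in place of 36.1%.

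In the rosette IL1B was lower at 24 h at log2 -3.59 ± 0.48 (adjusted p = 0.00301) and relaxin receptor 2 higher by 2.99 ± 0.46 (adjusted p = 0.0184). The receptor lost its call with the gland as a random block and under median scaling, each of which left 1 target, lower at 24 h. Inflammatory cytokines shifted down with 1 of 23 singly and 5 adjusted over the list alone (mean log2 -0.87 ± 0.20, adjusted p = 8.89e-08, and adjusted p = 0.0502 with an estimated correlation). Squamous markers were lower as a list with no member past the test over all targets or adjusted over the list alone (mean log2 -0.82 ± 0.69, adjusted p = 7.20e-08, and adjusted p = 0.181 with an estimated correlation), and at adjusted p = 0.319 without cow 2661. The remaining target past the test carries no protein name, and 3526 targets had an unadjusted p under 0.05. The count of 3, 2 of them higher, became 10 without cow 2661, 1 of them higher, 0 (3208 unadjusted) without cow 2829, 0 (3403 unadjusted) without cow 2851 and 2, both lower, without the E. coli 24 h array of cow 2661. It was 0 (2811 unadjusted) with the neutrophil covariate. With that covariate squamous markers stood at -0.78 (adjusted p = 2.40e-06 by camera). Markers of other tissue were higher at 24 h in that fit: smooth muscle by 0.60, fibroblast and collagen by 0.55 (both adjusted p = 8.78e-05) and endothelium by 0.35 (adjusted p = 0.0144). Whether the make-up of the sampled tissue differed between the times was not tested.

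In the gland cistern CCL20 was lower at 24 h at log2 -5.27 ± 0.97, CCL4 at -3.86 ± 0.55, IL6 at -3.76 ± 0.84, IL1B at -3.53 ± 0.48, IL1A at -3.49 ± 0.44 and TNF at -3.48 ± 0.79 (adjusted p between 8.04e-04 and 0.0496). Inflammatory cytokines shifted down with 6 of 23 singly and 10 adjusted over the list alone (mean log2 -1.17 ± 0.20, adjusted p = 8.68e-10, and adjusted p = 0.0241 with an estimated correlation). CXCR2 at -0.22 ± 0.38 (adjusted p = 0.839) and HP at -0.22 ± 0.64 (adjusted p = 0.912) did not pass. Each named gene lost its call without cow 2851. Between the times 150 targets differed, 93 of them lower at 24 h. Without cow 2661, 2829 or 2851 the count was 426, 3 or 0 (5053 unadjusted), and with the gland cistern arrays alone 0 (3857 unadjusted). For targets above the median target only, the larger direction turned, with 82 of 152 higher at 24 h. Without the 12 h gland cistern array of cow 2661, left out after the results were seen, the count was 661, and with the neutrophil covariate it was 10. With that covariate cytokines stood at -0.87 (adjusted p = 4.87e-06 by camera). Tissue markers were higher at 24 h in that fit: smooth muscle by 0.58 (adjusted p = 0.00859), fibroblast and collagen by 0.53 (adjusted p = 0.0110) and squamous by 0.62 (adjusted p = 0.0135). A difference in tissue make-up between these glands was not tested.

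In lobuloalveolar tissue neutrophil and acute phase genes were higher at the later time. GW112 protein, a granule protein of neutrophils, was higher at 24 h than at 12 h by log2 4.93 ± 0.51, IL1R2 by 4.74 ± 0.38, CXCR2 by 4.21 ± 0.38, HP by 3.70 ± 0.64 at the brightest of its 3 targets (the others having the opposite sign), IL10 by 3.01 ± 0.48 and S100A9 by 2.64 ± 0.44 (adjusted p at most 4.65e-04). FASN was lower at -4.05 ± 0.84, cytochrome P450 2B11 at -4.33 ± 0.77 and the prostaglandin-degrading 15-hydroxyprostaglandin dehydrogenase at -3.79 ± 0.81 (adjusted p at most 0.00341). IL1B at 1.44 ± 0.48 (adjusted p = 0.07) and CCL20 at 0.92 ± 0.97 (adjusted p = 0.693) did not pass. Antimicrobial and acute phase genes were higher in 15 of 30 cases, 17 adjusted over the list alone (mean log2 1.35 ± 0.15, adjusted p = 2.02e-09, and adjusted p = 0.0218 with an estimated correlation). Neutrophil markers were higher in 8 of 15, while adjusted over the list alone 8 were higher and 1 lower (mean log2 1.48 ± 0.40, adjusted p = 1.21e-06, and adjusted p = 0.0579 with an estimated correlation). IL10, S100A9, FASN and the dehydrogenase lost their calls without cow 2829, the latter pair also without cow 2851. The count was 3223, 2156 of them higher at 24 h, and 610 without cow 2829 and 1609 without cow 2851. With neutrophil transcripts as a covariate, chosen after seeing the data, 15 targets passed and the antimicrobial list stood at 0.55 (adjusted p = 0.0427). Times and glands coincide here, since the 12 h and 24 h samples of a cow come from different glands.

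Whether the teat regions respond differently from lobuloalveolar tissue was tested directly, as the mean response of rosette and teat cistern minus the lobuloalveolar response. At 12 h the collagenase MMP1 responded more in the teat regions by log2 3.64 ± 0.56 (adjusted p = 0.0138), while CCL20 at 5.38 ± 1.19 (adjusted p = 0.258) and IL1B at 3.32 ± 0.59 (adjusted p = 0.0986) did not pass. As a list the inflammatory cytokines responded more in the teat regions, none of 23 singly and 8 adjusted over the list alone (mean log2 1.16 ± 0.10, adjusted p = 1.08e-16, and adjusted p = 0.00163 with an estimated correlation). The chemokine list did so too, none of 22 singly and 8 adjusted over the list alone (mean log2 1.28 ± 0.06, adjusted p = 1.95e-11, and adjusted p = 0.0207 with an estimated correlation). The neutrophil list followed, none of 15 singly and 3 adjusted over the list alone (mean log2 0.94 ± 0.05, adjusted p = 1.15e-07, and adjusted p = 0.0289 with an estimated correlation). Its mean change was 0.85 in the rosette, 2.82 in the teat cistern and 0.89 in lobuloalveolar tissue. The neutrophil difference thus came from the teat cistern, and the rosette did not exceed lobuloalveolar tissue. Only 2 targets passed in this fit, MMP1 and a target without a protein name, with 1718 at an unadjusted p under 0.05. Without cow 2661, 2829 or 2851 the count was 0 (2208 unadjusted), 0 (1365 unadjusted) and 0 (1720 unadjusted). With the neutrophil covariate it was 0 (2569 unadjusted), and the means were 0.64 for cytokines (adjusted p = 0.00251) and 0.63 for chemokines (adjusted p = 0.0122).

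At 24 h neutrophil and acute phase genes responded less in the mean of rosette and teat cistern than in lobuloalveolar tissue. The difference was log2 -5.09 ± 0.46 for CXCR2, PTGS2 stood at -4.58 ± 0.86, IL1R2 at -4.47 ± 0.47 and neutrophil beta-defensin 4 at -4.47 ± 0.50. Smaller differences were those of HP at -3.30 ± 0.79, S100A8 at -2.75 ± 0.51, S100A9 at -2.48 ± 0.54 and IL10 at -2.29 ± 0.59 (adjusted p of these genes between 1.14e-06 and 0.0343). For CXCR2, S100A8 and S100A9 the rosette already held high levels in PBS glands. The regions behind the mean were unlike. S100A8 changed by -0.36 in the rosette and 5.01 in the teat cistern, and CXCR2 by -0.04 and 4.06, against 7.10 for CXCR2 in lobuloalveolar tissue. The neutrophil list stood at 1.97 in the teat cistern and 2.37 in lobuloalveolar tissue, so its lower mean lay mostly with the rosette. Differences in the other direction were found for the FAM13C1 protein at 4.02 ± 0.88, LPL at 3.13 ± 0.82, heparanase at 3.10 ± 0.77, CR2 at 2.49 ± 0.48 and follistatin at 2.43 ± 0.52 (adjusted p at most 0.0399). Antimicrobial and acute phase genes responded less in the teat regions in 10 of 30 cases, and adjusted over the list alone in 11 against 1 the other way (mean log2 -1.10 ± 0.03, adjusted p = 1.15e-07, and adjusted p = 0.0207 with an estimated correlation). Neutrophil markers responded less in 5 of 15, 6 adjusted over the list alone (mean log2 -1.20 ± 0.16, adjusted p = 1.07e-05, and adjusted p = 0.0687 with an estimated correlation). CXCR2 and IL1R2 also passed with any 1 cow left out, and each other named gene lost its call without at least 1 cow. The test found 1052 targets, 251 with a higher and 801 with a lower response in the teat regions. With the neutrophil covariate the antimicrobial mean was -0.46 (adjusted p = 0.0447). The count was 8 with that covariate, 5 without cow 2829, 172 without cow 2851 and 1813 with the arrays of these 3 regions alone.

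**Figure D4:**
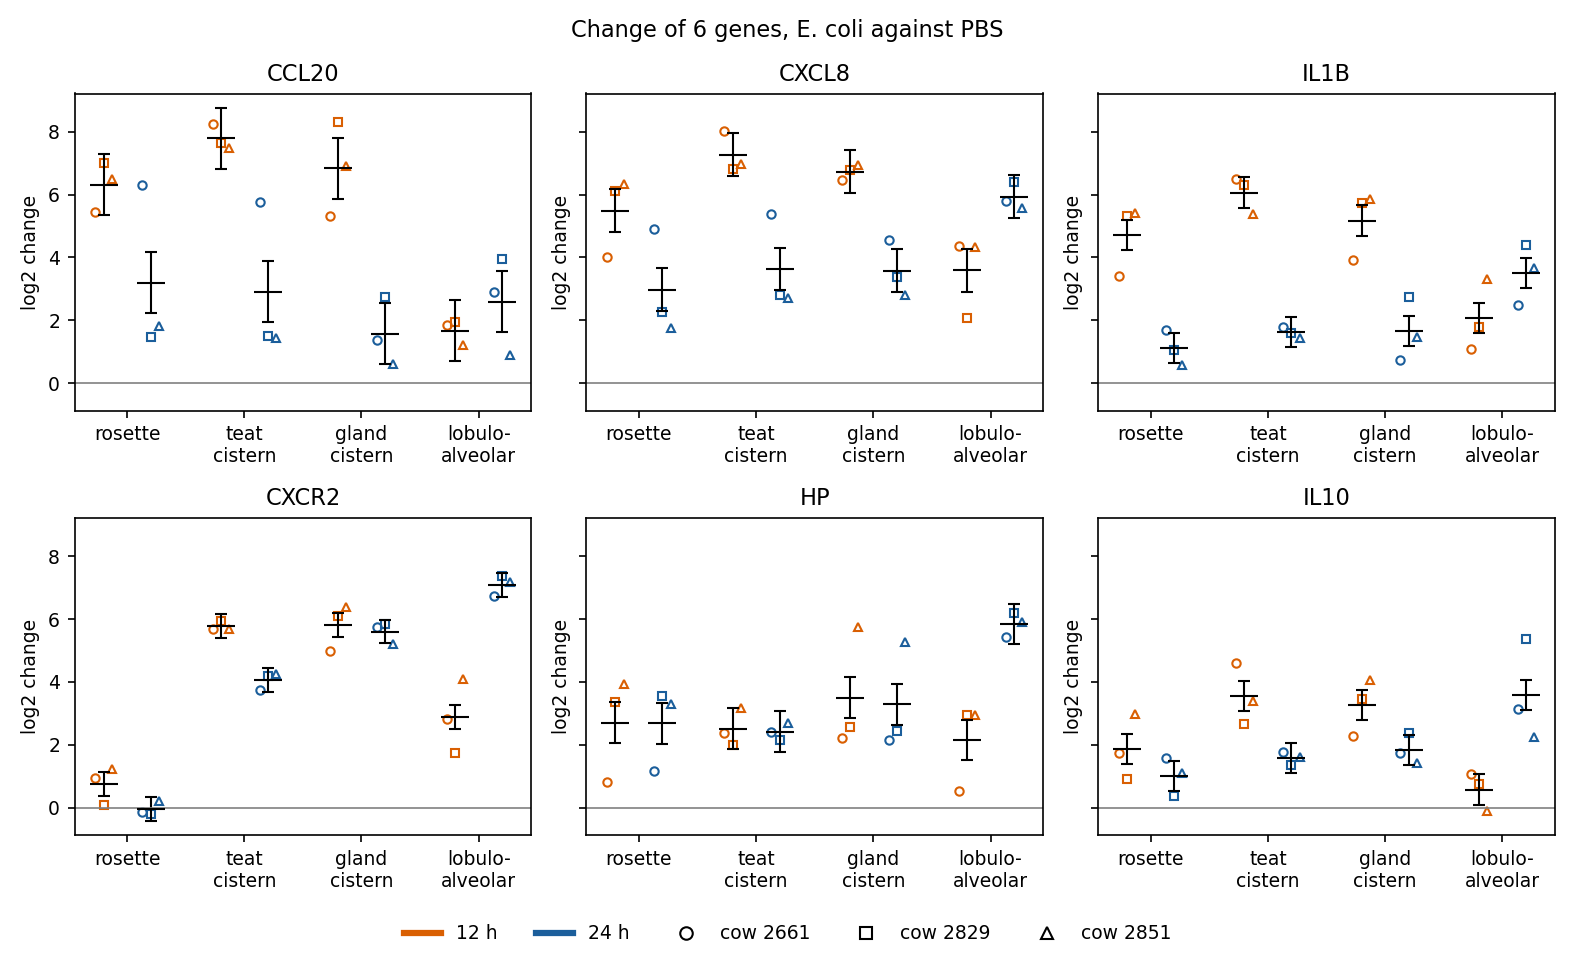
Log2 change of 6 genes in E. coli against PBS glands by region at 12 h and 24 h; open symbols are the 3 cows and black bars the fitted change with its standard error. CXCR2 stood at 7.10 in lobuloalveolar tissue and at -0.04 in the rosette at 24 h.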

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

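In this part the tests of the normalization for the 24 h response difference and of the slope between regions were chosen only after the result was seen, as was the covariate of neutrophil transcripts as an alternative.

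A direct test found regions or times that differed in their response. Between E. coli glands at 24 h and 12 h, 3 targets differed in the rosette, 133 in the teat cistern, 150 in the gland cistern and 3223 in lobuloalveolar tissue. The response of the teat regions differed from that of lobuloalveolar tissue for 2 targets at 12 h and 1052 at 24 h. Without cows 2661, 2829 and 2851 in turn the counts between the times were 10, 0 (3208 unadjusted) and 0 (3403 unadjusted) in the rosette, 349, 2 and 6 in the teat cistern, 426, 3 and 0 (5053 unadjusted) in the gland cistern, and 2343, 610 and 1609 in lobuloalveolar tissue. For the response difference they were 0 (2208 unadjusted), 0 (1365 unadjusted) and 0 (1720 unadjusted) at 12 h and 1039, 5 and 172 at 24 h, where unadjusted counts p under 0.05 in limma. At 12 h the interstitial collagenase MMP1 responded more in the teat regions by log2 3.64. At 24 h the response of the teat regions was higher for FAM13C1 (log2 4.02), lipoprotein lipase (3.13), heparanase (3.10), CR2 (2.49), DTTR431, a clone-like name of no known role (2.47), and follistatin (2.43). It was lower for IL10 (-2.29), S100A9 (-2.48), S100A8 (-2.75), HP (-3.30), neutrophil beta-defensin 4 (-4.47), IL1R2 (-4.47), embryonic poly(A) binding protein (-4.47), ankyrin repeat SOCS box protein 5 (-4.56), PTGS2 (-4.58) and CXCR2 (-5.09), each in the same direction in 3 of 3 cows. These values take the mean of rosette and teat cistern, which could be unlike: S100A8 changed by -0.36 in the rosette and 5.01 in the teat cistern.

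Among gene lists, 15 differed in response at 12 h. Higher in the mean of the teat regions were inflammatory cytokines (mean log2 1.16), chemokines (1.28), neutrophil markers (0.94), matrix remodelling (0.75), leukocyte adhesion (0.73), NF-kB targets (0.72), antimicrobial and acute phase genes (0.69), monocyte markers (0.60), interferon-stimulated genes (0.51), apoptosis (0.29) and pattern recognition (0.22). Neutrophil markers changed by 0.85 in the rosette, 2.82 in the teat cistern and 0.89 in lobuloalveolar tissue, so the rosette was not higher. Milk proteins (-0.95), luminal epithelium (-0.61), tight junctions (-0.43) and smooth muscle (-0.29) were lower. At 24 h 14 lists differed, with neutrophil markers (-1.20), antimicrobial and acute phase genes (-1.10), inflammatory cytokines (-0.96), squamous markers (-0.82), NF-kB targets (-0.78), leukocyte adhesion (-0.78), immediate early genes (-0.75), matrix remodelling (-0.60), pattern recognition (-0.44) and cell cycle genes (-0.44) lower in the teat regions. Fibroblast and collagen genes (0.74), sterol synthesis (0.65), milk lipid and lactose synthesis (0.42) and T and NK cell markers (0.37) were higher. Neutrophil markers stood at 1.97 in the teat cistern and 2.37 in lobuloalveolar tissue at 24 h, so their lower mean lay mostly with the rosette. With an estimated correlation 6 of these 29 shifts passed: at 12 h inflammatory cytokines (adjusted p = 0.00163), chemokines (0.0207), antimicrobial genes (0.0207), neutrophil markers (0.0289) and leukocyte adhesion (0.0420), and at 24 h antimicrobial genes (0.0207). With the neutrophil covariate the 12 h calls of antimicrobial genes (mean log2 0.18, adjusted p = 0.280) and leukocyte adhesion (0.19, adjusted p = 0.107) ended, and cytokines (0.64, adjusted p = 0.00251) and chemokines (0.63, adjusted p = 0.0122) passed at smaller means.

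For the larger lobuloalveolar response at 24 h, led by CXCR2 and PTGS2, a larger spread between arrays of the teat regions was considered. Their median residual SD was 0.896 times that of lobuloalveolar tissue, each region fitted alone. This ratio cannot bear on calls made with a pooled spread, so it decides nothing here. Under median scaling 915 targets differed, which argues against the quantile normalization (but 5 differed without cow 2829 and 172 without cow 2851 in the main normalization). The authors' values, of unstated processing, gave 844, and 1184 differed without background correction, which keeps the quantile normalization. With neutrophil transcripts as a covariate 8 of 1052 targets passed, under the tenth that was set before this fit as the sign of neutrophil number, but the median size fell from log2 1.71 to 1.15 while the median SE grew from 0.38 to 0.50 and 1045 of 1052 kept their sign, so a condition on the size, added after this was seen, was not met. PTGS2 was -4.58 ± 0.86 before and -5.22 ± 1.24 after, IL1R2 -4.47 ± 0.47 and -3.56 ± 0.63, IL10 -2.29 ± 0.59 and -0.11 ± 0.60, and CXCR2, itself on the list behind the covariate, -5.09 ± 0.46 and -3.47 ± 0.50. Of the 14 lists 6 still passed in the same direction, among them antimicrobial and acute phase genes, from -1.10 to -0.46 (adjusted p = 0.0447), and, with means that moved little, fibroblast and collagen genes (0.74 before and after, adjusted p = 0.00135), immediate early genes (-0.75 and -0.70, adjusted p = 0.00251) and squamous markers (-0.82 and -0.72, adjusted p = 0.0302), where the calls of the last 3 without the covariate were lost with an estimated correlation (adjusted p = 0.401, 0.156 and 0.448), while inflammatory cytokines went from -0.96 to -0.29 (adjusted p = 0.378). IL10 and the decoy receptor IL1R2, whose differences are given above, are members of this cytokine list. More neutrophils and a change within cells cannot be told apart for the targets as a whole, since their errors grew with the covariate. The region itself and the gland stay open as untested explanations.

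Fewer neutrophils were considered as an explanation of the lower inflammatory cytokine transcripts at 24 h in the teat cistern, IL1B and IL6 among them. With the neutrophil covariate the list mean moved from -1.41 to -0.93 at adjusted p = 9.53e-07 by camera. The list kept its sign, most of its size and its call, the outcome set before this fit as the sign against neutrophil number. The covariate is a mean of transcripts, among them S100A8 and S100A9, which keratinocytes also carry. It may follow neutrophil number incompletely, so the remaining difference does not decide whether neutrophil number is the whole, a part or no part of the cause. The highest adjusted p of this list by camera was 8.58e-15 over median scaling, no background correction and the authors' values. This argues against the quantile normalization, which median scaling replaces. The 12 h and 24 h samples of a cow come from different glands. The gland and the make-up of the sampled tissue stay open as untested explanations.

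The few calls in the rosette at 12 h, CXCL8 and CCL20 among them (84, and 6 without cow 2851), may follow from smaller changes there. Over the 4970 targets called in the teat cistern the slope of the rosette change was 0.368, against 0.750 in the gland cistern and 0.307 in lobuloalveolar tissue, and 4316 had the same direction in the rosette. The median residual SD of the rosette was 1.07 times that of the teat cistern, each fitted alone, which cannot bear on calls made with a pooled spread. Targets picked for passing in the teat cistern favour larger changes there, which lowers the slope of every other region. The region itself is an untested explanation.

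Other splits of the 6 samples of each comparison were counted with limma, 10 per comparison, which are too few for a share under 0.05. The real count and the highest other were 84 and 0 for the rosette at 12 h, 4970 and 0 for the teat cistern, 5546 and 3229 for the gland cistern and 8 and 30 for lobuloalveolar tissue. At 24 h they were 5 and 3, 602 and 0, 309 and 58, and 6054 and 0 in the same order. For 24 h against 12 h they were 3 and 12, 133 and 1, 150 and 525, and 3223 and 7. For response differences taken per cow without a block they were 1 and 0 at 12 h and 1343 and 0 at 24 h. Between PBS regions they were 13629 and 0 for the rosette, 14124 and 1 for the teat cistern and 563 and 1168 for the gland cistern. A count as large as the real one came from 1 split, the real one, except 2 splits for lobuloalveolar tissue at 12 h, 3 for the rosette and 2 for the gland cistern between the times, and 2 for the PBS gland cistern. The split with 3229 parted the samples of every cow, as the real one does, and those with 525 and 1168 did not. What these splits reflect was not tested.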

How the results depend on the processing

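The covariate of neutrophil transcripts and the omission of 2 arrays of cow 2661 are tests chosen only after the result was seen. Counts not given here were within 1.5 times those in the comparisons. Where a count was 0, the number at an unadjusted p under 0.05 in limma follows it, and except where stated the cause was not tested.

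Without a term for cow, CXCR2 and the other genes were tested against a spread that includes the cows. The counts at 12 h were 53 in the rosette, 3006 in the teat cistern, 3202 in the gland cistern and 5 in lobuloalveolar tissue. At 24 h they were 267 in the teat and 145 in the gland cistern, between the times 54 and 42 in these cisterns and 2126 in lobuloalveolar tissue. Response differences numbered 0 (1189 unadjusted) at 12 h and 634 at 24 h, and the PBS gland cistern had 14 targets. With the arrays of the compared regions alone, fewer samples estimate the spread. The rosette gave 0 (2832 unadjusted) at 12 h, 0 (2376 unadjusted) at 24 h and 0 (4256 unadjusted) between the times, the gland cistern 227, 11 and 0 (3857 unadjusted), lobuloalveolar tissue at 12 h 2, the response differences 1 and 1813, and the PBS gland cistern 0 (7942 unadjusted). With the gland as a random block in place of the cow (consensus correlation 0.273), the 12 h counts were 49, 3026, 3298 and 3 from rosette to lobuloalveolar tissue. The 24 h counts were 2, 285 and 112 in rosette, teat and gland cistern, those between the times 1, 54, 37 and 2133, and the response difference at 12 h gave 14 and the PBS gland cistern 2416.

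Under median scaling the median difference of all targets was furthest from 0 for the PBS rosette, at log2 -0.28 against -0.065 in the main fit. Median scaling gave 1 target between the times in the rosette, 5 response differences at 12 h and 845 targets in the PBS gland cistern. Under it 33.2% of the targets that differed in the PBS rosette were higher, against 48.7%, in the PBS teat cistern 41.7% against 51.7%, in the PBS gland cistern 16.7% against 41.6%, in the gland cistern at 12 h 57.6% against 49.8%, and between the times in the teat cistern 25% against 36.1%. No background correction gave 49 in the rosette at 12 h, 3 at 24 h and 201 between the times in the teat cistern, and 8 in lobuloalveolar tissue at 12 h, of which 5 are shared with the main fit and 62.5% were higher, against 100% in the main fit. The authors' values also gave 8 there, 5 of them shared and 87.5% higher. The authors' values gave 127 and 2 in the rosette at 12 h and 24 h, 80 between the times in the gland cistern, 1 response difference at 12 h and 18 in the PBS gland cistern. The share higher at 24 h was 77.9% against 65.3% in the teat and 82.6% against 72.5% in the gland cistern. With the 22627 targets above the median target only, fewer targets were tested, and the counts were 374 in the teat cistern and 4020 in lobuloalveolar tissue at 24 h, 1 between the times in the rosette, 1 and 617 for response differences, 8054 for the PBS rosette and 8688 for the PBS teat cistern. Under that filter the larger direction turned in 4 comparisons, with 55.9% higher against 36.1% between the times in the teat cistern, 53.9% against 38% in the gland cistern, 57.4% against 41.6% in the PBS gland cistern and 50.7% against 48.7% in the PBS rosette. With the neutrophil covariate the counts between the times were 0 (2811 unadjusted), 0 (4187 unadjusted), 10 and 15 from rosette to lobuloalveolar tissue, and for response differences 0 (2569 unadjusted) and 8.

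Leaving out a cow or an array gave ranges of 6 to 88, 1783 to 1962, 417 to 7204 and 0 to 11 targets at 12 h from rosette to lobuloalveolar tissue, and 0 to 4, 34 to 150, 53 to 230 and 1984 to 5146 at 24 h. Between the times the ranges were 0 to 10, 2 to 349, 0 to 661 and 610 to 2343. Response differences ranged from 0 to 0 at 12 h and from 5 to 1217 at 24 h, PBS regions from 7204 to 11287, 7770 to 11553 and 0 to 1565, and list shifts from 220 to 239 against 237. Similar counts can hold other targets: the 88 of the rosette at 12 h, without cow 2829, share 34 with the main fit and are 29.5% higher against 82.1%, and the 11 of lobuloalveolar tissue, without cow 2661, share 0. An array left as 1 of 2 in its group is assumed to vary like the other groups.

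Of the 237 list shifts, those past the test in the same direction numbered between 225 and 232 under the 7 alternatives of fit, normalization and gene representation, 202, 201 and 209 without cows 2661, 2829 and 2851, and 36 with an estimated correlation. Sterol synthesis in the gland cistern at 24 h turned its direction without cow 2851 (adjusted p = 0.863, against 1.60e-06 without cow 2829). In the PBS teat cistern COX4I1 turned to log2 -0.039 with the authors' values, and LOR to 0.099 with the mean of all targets. Of 1597 values of genes under the naming rule, 1380 to 1560 stayed on the same side of the test across the 7 alternatives, and 302 lost their call without cow 2829, 242 without cow 2851 and 152 without cow 2661. Tests of each probe alone were not run, since the files give no probe values, nor was a slide or scan term, since each array has its own scan. The files hold no control probes, so signal over background could only be judged against the median target. Casein and LALBA intensities near the top of the scale limit what changes of milk protein genes can be seen.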

Other observations

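The tests that leave out 2 arrays of cow 2661 were chosen only after the result was seen, on the following values, which are changes against PBS and so do not single out an array. In the rosette at 24 h the squamous list changed against PBS by mean log2 -1.54 in cow 2661, -0.20 in cow 2829 and 0.18 in cow 2851. In the gland cistern at 12 h the fibroblast and collagen list stood at -1.52, -0.47 and 1.03 in cows 2661, 2829 and 2851, and the smooth muscle list at -0.93, -0.57 and 0.60. In both of these lists cow 2851 lay further from the middle cow than cow 2661 did. Leaving out the gland cistern array of cow 2661 gave 6266 changed targets at 12 h, and leaving out the rosette array of cow 2661 gave 1217 response differences at 24 h.

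Over all arrays the leading component held 31.4% of the variance, 87.5% of it between regions, and the next 18%, 81.7% of it between regions. The third component, 11.7%, lay 60.8% between treatments, the fourth, 7.39%, lay 47% between cows, and the fifth, 4.68%, lay 70.7% between cows. Arrays of the same cow and gland correlated in their deviations from group means at a mean r of 0.317 over 54 pairs. For arrays of the same cow from other glands the mean r was 0.194 over 144 pairs.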
